A study of Mus musculus with 9 samples.

How the data were processed

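RNA was sequenced from cultured mouse macrophages grown from the bone marrow of C57BL/6 animals aged 8 weeks and kept in RPMI medium. Per the labels, cells received 15d-PGJ2 (15-deoxy-Δ12,14-prostaglandin J2, a cyclopentenone prostaglandin) at 1 µM, a compound written 15d-PGJ2-PC at 1 µM, or medium only, and were collected after 6 h. The labels do not spell out PC, so no structure is given for that compound here. Each of the 3 groups has 3 libraries, 9 in all. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with Illumina's TruSeq RNA kit. The labels call the 3 libraries of a group replicates without saying whether they come from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical.

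The authors deposited 1 table of FPKM values (fragment counts scaled to gene length and sequencing depth), per the file headers, for 18049 genes with an Entrez number and a RefSeq transcript list. Genome build mm10 and the aligner BWA come from the submitters' processing notes; the version of BWA and the tool that counted reads per gene are not given in the sources used here. FPKM values were used as deposited, with 2 decimals and no further scaling. All sample columns of the table were used. A spreadsheet had turned 23 gene symbols into dates, and all 23 were restored from the Entrez number. Of the Entrez numbers, 18000 were found in the reference annotation of the same build (GRCm38, the assembly that mm10 names), which supplied 1-based gene coordinates. Lengths, for 17704 genes, were medians over GENCODE transcripts matched by RefSeq accession. Of the tested genes, 98.9% have a length.

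FPKM is not a count, so no count model was used. The value of 1 read was read off the smallest steps between low values of short genes (82 genes, tolerance 0.06 of a step), and gave about 5.60 M reads per library (95% interval 5.56 to 5.63). Steps differed between libraries by factors of 0.989 to 1.01, and sums over genes with a length gave 5.69 to 5.74 M reads per library. At that depth a gene with 20 to 100 reads varied within a group by 6.4% to 7.8% (coefficient of variation beyond counting noise) and one with 2000 to 10000 reads by 2.0% to 3.2%.

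Genes with at least 1 FPKM in at least 3 of the 9 libraries were tested, 11309 in all. Values were moved to log2(FPKM + 1), so a fold change understates that of genes near or below 1 FPKM. The test was limma's moderated test with an intensity trend (limma 3.58.1 in R 4.3.3), 2-sided, with 1 residual variance per gene over all 9 libraries and no covariate. P-values were adjusted by the Benjamini-Hochberg method within each contrast, with a threshold of 0.05. Every adjusted p of a gene is from this test unless another is named. The contrasts were 15d-PGJ2 against control, 15d-PGJ2-PC against control, and 15d-PGJ2-PC against 15d-PGJ2, at the same dose and time.

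Before the data were examined, 33 gene lists were fixed, 19 of pathways and 14 of cell type markers or signs of RNA quality, with 655 members, of which 622 were listed in the table and 514 tested. Lists with at least 3 tested members (29) were tested with limma's camera at a preset correlation of 0.01, adjusted over the 29 lists of a contrast; camera with an estimated correlation and limma's fry were alternatives. Fry asks whether a list's genes move, on balance, one way and does not compare them with other genes. A list score is the mean of log2(FPKM + 1) over the tested members in a library. Its difference between groups has a 95% interval from a linear model over the 9 libraries and an exact 2-sided permutation test, whose smallest possible p with 3 against 3 libraries is 0.1. Ratios of score differences have jackknife standard errors. An unlogged score is the geometric mean of FPKM + 1 over the same members, and ratios of unlogged scores come from the score differences. Values are means ± SD over 3 libraries, and log2 fold changes carry standard errors (SE).

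The genes to name were also fixed by rule: per contrast, the 10 largest rises and the 10 largest falls among genes that passed, whose 3 libraries of one group all lay above or below the 3 of the other and whose higher mean was at least 1 FPKM; the up to 4 members of each pathway list with the smallest p; and 20 genes regardless of their result. Some genes that this rule takes are not reported here. Any other gene named was chosen after its values were seen, and so were the RNAs without poly(A) tails. The lists of skin transcripts and the gene families formed from gene descriptions were made after the data were seen. A further set of skin genes was picked without looking at the values of its members. Names ending in Rik, gene models, pseudogenes, microRNAs and snoRNAs are counted but not named. Genes with near-identical copies (Hspa1a and Hspa1b, Hist1h2bq and Hist1h2br, Ifit3 and Ifit3b, Hba-a1 and its copy) share reads, so their individual values are uncertain; Slfn5 and its antisense gene Slfn5os cannot be told apart without strand information, which is not given in the sources used here.

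The responses to both compounds share the control libraries, so their correlation was set beside 200 simulations of unchanged groups against those controls; 3 controls are too few to be divided into sets of at least 2. The test was tried on simulated data for 15d-PGJ2 against control with 11121 genes fitted. It recovered 18% of genes changed 1.25-fold, 66% of those changed 1.5-fold, 81.6% of those changed 2-fold and 98% of those changed 4-fold, with 8 false calls among 139. No random list of 100 was called. The simulation held 199 changed genes and a 5% coefficient of variation beyond counting noise. In the data 5338 genes were called, and the Benjamini-Hochberg cutoff depends on that number, so the recovery rates cannot be carried over to the data. Simulated genes were drawn independently, so the random lists cannot show how camera treats lists of correlated genes. Alternatives were other pseudocounts, filters and scalings, limma without the trend, with robust priors or array weights, the 6 libraries of a contrast alone, the replicate number as a block, each library left out in turn, stricter and looser thresholds and, for lists, the other tests named above. A pair of alternatives was added after the data were seen: genes with a mean of at least 20 FPKM, and leaving out genes seen in controls only. Samples were compared before they were averaged: pairs within a group differed by 1.37 to 2.96 times counting noise over genes with at least 100 reads (mean squared difference), so no library was a copy of another. No test for outlying libraries was made beyond array weights and leaving out each library in turn. The 13 genes of the mitochondrial genome were not analysed here. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and plots.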

Results

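Gene expression was measured in 9 RNA libraries of mouse bone marrow-derived macrophages exposed for 6 h to 1 µM 15d-PGJ2 (3 libraries), 1 µM 15d-PGJ2-PC (3 libraries) or medium (3 control libraries). 15d-PGJ2 is an electrophilic prostaglandin, a known ligand of PPARγ and activator of the antioxidant factor Nrf2, and the design asks how macrophage transcripts respond to it and to the related compound. Libraries held about 5.60 M reads each, with 14459 to 15277 genes above 0 and 10876 to 11026 genes at 1 FPKM or more. Summed FPKM ran from 469548 to 492998 per library. Log2 values correlated across genes, which are not independent replicates, at 0.987 to 0.989 within groups and at 0.944 to 0.979 between groups. On the first principal component, with 58.3% of the variance, control libraries scored -31.8 to -30.0, 15d-PGJ2-PC libraries 2.45 to 3.58 and 15d-PGJ2 libraries 26.0 to 29.6. The second, with 9.4%, set 15d-PGJ2-PC libraries (-14.5 to -12.1) apart from controls (4.65 to 7.65) and 15d-PGJ2 libraries (6.9 to 8.57).

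With 15d-PGJ2, 28 of 30 Nrf2 targets and all tested heat shock and proteasome genes rose, and 30 of 31 type I interferon-induced genes, 16 of 18 endoplasmic reticulum genes and 17 of 18 macrophage markers fell, against control. With an estimated correlation the list calls of heat shock genes, interferon-induced genes and macrophage markers were lost (adjusted p = 0.0871, 0.0835 and 0.0835). Hmox1, which encodes heme oxygenase 1, rose from 332 ± 8.11 to 6540.1 ± 124 FPKM (SD, n = 3 per group), a 19.6-fold change. The inducible chaperone gene Hspa1b rose from 4.46 ± 0.81 to 837 ± 158 FPKM, and Psma5, a subunit of the proteasome core, from 70.4 ± 3.62 to 180 ± 3.42 FPKM. Ifit3, an interferon-induced antiviral gene, fell from 341 ± 48.4 to 19.5 ± 1.00 FPKM. Limma called 5338 of the 11309 tested genes (47.2%): 2515 rose, 311 of them at least 2-fold, and 2823 fell, 387 of them at least 2-fold. The 3 libraries of one group all lay above or below those of the other for 6232 genes (55.1%), where chance gives 10%.

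Among Nrf2 targets, genes of glutathione and thioredoxin metabolism and iron handling, 28 of 30 tested members rose, 1 fell and 1 did not pass, with the same counts adjusted over the list alone (median log2 fold change 1.36, camera adjusted p = 4.78e-24). Hmox1 (Entrez 15368, GRCm38 chromosome 8, 75093618 to 75100593) changed by 4.30 on the log2 scale (SE 0.03, adjusted p = 1.18e-14). Gclm, the modifier subunit of glutamate-cysteine ligase (Entrez 14630, chromosome 3, 122245487 to 122267215), rose from 62.8 ± 2.55 to 486 ± 3.77 FPKM. Srxn1 (sulfiredoxin) rose from 61.6 to 448 FPKM, Txnrd1 (thioredoxin reductase) from 98.3 to 397, the cystine transporter gene Slc7a11 from 26.6 to 61.1 and the quinone reductase gene Nqo1 from 2.37 to 11.5. Ugdh fell by 0.75 on the log2 scale and Ephx1 was at 8.40 and 9.17 FPKM (adjusted p = 0.402). Both were named after their values were seen. Nfe2l2, which encodes Nrf2 itself, was at 77.5 and 78.6 FPKM (adjusted p = 0.74). The list member Me1, malic enzyme (3.05 to 28.6 FPKM), was among the largest rises. So were, outside the list, the cell cycle inhibitor gene Cdkn2b (2.04 to 31.8) and aldehyde oxidase Aox1 (0.72 to 11.4).

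All 21 tested heat shock genes rose, also adjusted over the list alone, with a median log2 fold change of 1.92 (camera adjusted p = 4.19e-20, adjusted p = 0.0871 with an estimated correlation). Hspa1b (Entrez 15511, chromosome 17, 34956429 to 34959238) changed by 7.25 (SE 0.15, adjusted p = 2.32e-10) and its near-identical neighbour Hspa1a (Entrez 193740, chromosome 17, 34969359 to 34972156) by 6.92. Reads may be split between them. Hspb1, a small heat shock protein gene (Entrez 15507, chromosome 5, 135887919 to 135889563), rose from 3.89 ± 0.97 to 186 ± 43.8 FPKM and the co-chaperone gene Hsph1 from 11.2 ± 0.86 to 232 ± 41.0. The abundant chaperone genes Hspa8 (923 to 3311 FPKM) and Hsp90ab1 (456 to 1731) rose by 1.84 and 1.92 on the log2 scale, and Dnaja4 rose from 0.34 to 8.85 FPKM. All 31 proteasome subunit genes rose as well, with the same count adjusted over the list alone (median 0.95, camera adjusted p = 1.92e-21). Psma5 (Entrez 26442, chromosome 3, 108256926 to 108279952) changed by 1.34 (SE 0.04), Psma7 by 1.16, and the regulatory particle genes Psmd11 and Psmd2 by 1.36 and 0.91.

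**Figure D1:**
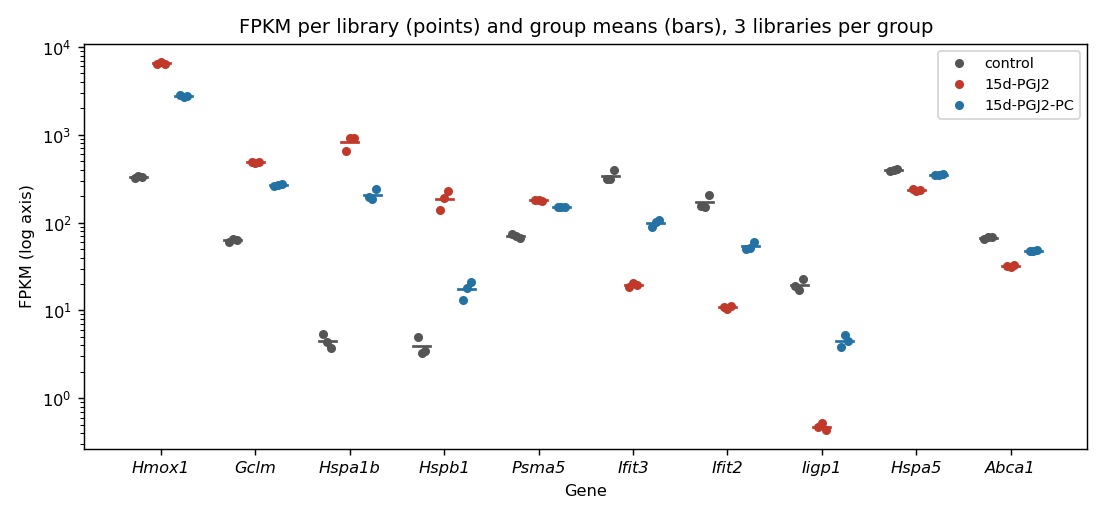
FPKM (log axis) of 10 named genes in each of the 9 libraries, with a point per library and a bar at the mean of each group of 3. Hmox1, Gclm, heat shock genes and Psma5 were highest with 15d-PGJ2, and Ifit3, Ifit2, Iigp1, Hspa5 and Abca1 were lowest with it, with 15d-PGJ2-PC between.

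Of 31 tested type I interferon-induced genes, 30 fell and 1 did not pass, also adjusted over the list alone, with a median log2 fold change of -1.84 (camera adjusted p = 2.95e-21, adjusted p = 0.0835 with an estimated correlation). Ifit3 (Entrez 15959, chromosome 19, 34583119 to 34588982) fell by 4.05 (SE 0.09, adjusted p = 4.98e-10), with reads possibly shared with Ifit3b, and Ifit2 (Entrez 15958, chromosome 19, 34550550 to 34576534) fell from 170 ± 32.7 to 10.9 ± 0.41 FPKM. Stat2, a transcription factor of interferon signalling, fell from 87.0 to 16.4 FPKM and the receptor-transporting protein gene Rtp4 from 136 to 31.3, while Isg20 was at 17.8 and 16.6 FPKM (adjusted p = 0.544, named after its value was seen). Of 15 genes of interferon-γ response and antigen presentation, 12 fell and 3 did not pass (the same adjusted over the list alone, median -0.74, camera adjusted p = 9.92e-07). Iigp1, an interferon-inducible GTPase (Entrez 60440, chromosome 18, 60373616 to 60392634), fell from 19.6 ± 2.84 to 0.47 ± 0.05 FPKM, and Irgm1, Gbp2 and the peptide transporter gene Tap1 fell by 1.97, 2.13 and 0.93 on the log2 scale. Cmpk2 (87.4 to 5.29 FPKM), Tgtp2 (33.5 to 1.92) and Pydc3 (42.1 to 4.21) were other large falls.

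Of 18 endoplasmic reticulum chaperone and unfolded protein response genes, 16 fell and 2 did not pass (17 fell adjusted over the list alone, median -0.47, camera adjusted p = 3.79e-08). Hspa5, which encodes the chaperone BiP (Entrez 14828, chromosome 2, 34772090 to 34776529), fell from 398.5 ± 6.85 to 234 ± 4.40 FPKM, and Herpud1, Pdia4 and Pdia6 fell by 0.85, 0.92 and 0.66 on the log2 scale. In the ATF4 list of the integrated stress response, 12 of 23 genes rose, 2 fell and 9 did not pass, the same adjusted over the list alone (median 0.23, camera adjusted p = 0.0015, adjusted p = 0.229 with an estimated correlation). The amino acid transporter chain gene Slc3a2 rose from 186 to 404 FPKM, Atf4 from 190.1 to 260 and Trib3 from 41.5 to 72.6. The ATF4 list had 1 fallen gene without control replicates 1 or 3 or 15d-PGJ2 replicate 2. Among 21 glycolysis and hypoxia genes, 12 rose, 4 fell and 5 did not pass (13 rose and 4 fell adjusted over the list alone, median 0.25, camera adjusted p = 0.00164, adjusted p = 0.0871 with an estimated correlation). The glucose transporter gene Slc2a1 (17.6 to 59.2 FPKM), Pkm (555 to 1072) and Aldoa (614 to 1032) rose, and Ndrg1, a hypoxia-induced gene, fell by 0.81 on the log2 scale.

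Of 15 targets of the sterol sensor LXR, 9 fell, 2 rose and 4 did not pass, the same adjusted over the list alone (median -0.32, camera adjusted p = 0.0233, adjusted p = 0.261 with an estimated correlation). Quantile normalization also ended this call (adjusted p = 0.0503, within a range of 0.00774 to 0.0503 over the other camera settings). The cholesterol exporter gene Abca1 (Entrez 11303, chromosome 4, 53030789 to 53159988) fell from 67.1 to 32.1 FPKM, Abcg1 from 78.1 to 43.0 and Nr1h3, which encodes LXRα, from 124 to 54.6. Without control replicates 2 or 3 or 15d-PGJ2 replicates 1 or 2, 1 LXR target rose. Of 23 cholesterol synthesis genes, 15 fell, 1 rose and 7 did not pass (16 fell and 1 rose adjusted over the list alone, median -0.42, camera adjusted p = 0.00164, adjusted p = 0.0954 with an estimated correlation). Idi1 fell from 4.26 to 1.02 FPKM and Fdps and Acat2 by 0.86 and 0.92 on the log2 scale. The PPAR target list, with 7 genes that rose, 3 that fell and 11 that did not pass, was not called (same counts adjusted over the list alone, median 0.05, camera adjusted p = 0.23). Its score differed by 0.14 on the log2 scale, with a 95% interval of 0.10 to 0.18 that excludes 0, and without control replicate 3 the genes that fell numbered 6. In that list Acadvl, Acadl and the scavenger receptor gene Cd36 rose by 0.99, 0.76 and 0.38, Plin2 fell by 0.24, and the fatty acid binding protein gene Fabp4 was at 15.2 and 15.7 FPKM (adjusted p = 0.737).

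Genes of NF-κB-driven inflammation moved both ways. Of 25 tested, 7 rose, 11 fell and 7 did not pass, the same adjusted over the list alone, and the list was not called (median -0.17, mean -0.01, camera adjusted p = 0.507). The neutrophil chemoattractant gene Cxcl2 rose from 4.55 to 32.5 FPKM and Ier3 from 19.1 to 48.7, while Nfkbiz, Il12b and Il1b fell by 0.94, 1.58 and 0.64 on the log2 scale. Tnf did not pass (adjusted p = 0.34). Il6 passed at adjusted p = 0.0296 but not without control replicate 1 (0.107), 15d-PGJ2 replicate 2 (0.0901) or 15d-PGJ2 replicate 3 (0.0776). A pseudocount of 0.1 also ended the Il6 call (0.0615, within a range of 0.0157 to 0.107 over the alternatives).

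Of 16 eicosanoid metabolism genes, 9 rose and 3 fell, also adjusted over the list alone, and the list was not called (camera adjusted p = 0.0708). In it the prostaglandin reductase gene Ptgr1 rose from 11.8 to 59.3 FPKM and the cyclooxygenase 1 gene Ptgs1 fell by 1.41. Alternative activation genes were not called (3 of 9 rose and 4 fell, also adjusted over the list alone, camera adjusted p = 0.622), with Tgm2 and Il10 falling by 0.47 and 1.26. Phospholipid uptake and remodelling genes (8 of 25 rose and 9 fell, also adjusted over the list alone, camera adjusted p = 0.916) included the scavenger receptor gene Marco, which rose by 0.46, and Pld4, which fell by 0.70. Of 23 lysosome and autophagy genes 8 rose and 8 fell (11 and 10 adjusted over the list alone, camera adjusted p = 0.568). Gabarapl1, an autophagosome gene, rose from 82.5 to 249 FPKM and the cathepsin gene Ctss fell by 0.37. Immediate early genes (4 of 14 rose and 5 fell, 4 and 6 adjusted over the list alone, camera adjusted p = 0.745) included Ppp1r15a, which rose by 1.42, and Btg2, which fell by 1.01. Of 26 oxidative phosphorylation genes 7 fell and none rose (6 adjusted over the list alone, camera adjusted p = 0.176), among them Sdhb by 0.30. Among 28 cell cycle genes 9 fell and none rose, also adjusted over the list alone (median -0.27, camera adjusted p = 0.0541), with Mcm6 and Top2a falling by 0.37 and 0.53. The cell cycle list passed without 15d-PGJ2-PC replicate 1, 2 or 3 (0.0483, 0.0496 and 0.0456, range 0.0456 to 0.273 over the alternatives), and 1 oxidative phosphorylation gene rose without control replicate 3. Score intervals excluded 0 for eicosanoid genes (0.28, 95% interval 0.21 to 0.36), alternative activation genes (-0.19, -0.32 to -0.06) and lysosome genes (0.10, 0.05 to 0.15), though camera did not call them. So did those of immediate early genes (-0.09, -0.18 to -0.01), oxidative phosphorylation genes (-0.09, -0.13 to -0.04) and cell cycle genes (-0.26, -0.35 to -0.17).

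Of the remaining genes fixed for every contrast, Mt1 and Pparg did not pass (adjusted p = 0.182 and 0.701). Mt2 rose by 0.11 (adjusted p = 0.0166) but did not pass without control replicate 2 (0.07), without 15d-PGJ2 replicate 3 (0.0696) or without the trend (0.0952, range 0.0074 to 0.0952 over the alternatives). Angptl4 rose by 0.24 (adjusted p = 0.0333), though not without control replicates 2 or 3 (0.126 and 0.0546) or 15d-PGJ2 replicates 1 or 3 (0.0978 and 0.105). The 6 libraries of the contrast alone gave it 0.0525 (range 0.0186 to 0.126).

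Markers of macrophages fell with these groups: 17 of 18 fell and Trem2 did not pass, the same adjusted over the list alone (median -0.55, camera adjusted p = 6.55e-10, adjusted p = 0.0835 with an estimated correlation). Members given as exceptions to a list, such as Trem2, were named after their values were seen. Stromal and haemoglobin transcripts and many transcripts of skin were higher in the controls. RNA of another tissue in the controls is a candidate explanation, taken up under the other observations. All 7 tested stromal markers fell, also adjusted over the list alone (median -1.42, camera adjusted p = 0.000167), from a summed 51.0 ± 3.95 to 15.5 ± 1.48 FPKM over 13 listed genes. Of 4 erythroid markers the haemoglobin genes Hba-a1, Hbb-bs and Hbb-bt fell, also adjusted over the list alone (median -2.18, camera adjusted p = 0.0402, adjusted p = 0.132 with an estimated correlation). That call was lost with quantile normalization (0.0503), a pseudocount of 0.1 (0.0695), no filter (0.139) and without 15d-PGJ2 replicate 2 (0.0554, range 0.0139 to 0.139). H19, an imprinted RNA of embryonic tissue, was at 15.1 FPKM in controls and 0.053 with 15d-PGJ2, and Hba-a1 at 16.4 and 0.44. The loricrin gene Lor, of the epidermis (Entrez 16939, chromosome 3, 92080271 to 92083142), was at 7.91 ± 0.57 FPKM in controls and listed at 0 in each treated library. In all, 61 genes lay above 0.5 FPKM in each control and under 0.3 in each treated library, 22 of them keratin or keratin-associated genes. Of these, 30 were tested and all 30 fell, which the rule that chose them nearly fixes. Leaving them out gave 5303 changed genes. Their highest control mean was 7.91 FPKM. By the same rule 7 genes were seen with 15d-PGJ2 only and 1 with 15d-PGJ2-PC only. Fallen genes with a control mean under 20 FPKM numbered 1386, and 1437 lay above it.

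Histone, structural noncoding and ribosomal protein RNAs were higher as lists. Replication histone genes rose in 6 of 8 cases, also adjusted over the list alone (median 0.81, camera adjusted p = 0.00289, adjusted p = 0.125 with an estimated correlation). Structural noncoding RNAs rose in 6 of 9, also adjusted over the list alone (median 0.80, camera adjusted p = 0.0031, adjusted p = 0.0792 with an estimated correlation). Ribosomal protein genes rose slightly in 18 of 29 cases (19 adjusted over the list alone, median 0.11, camera adjusted p = 0.000283, adjusted p = 0.417 with an estimated correlation). The ferritin genes Fth1 and Ftl1, singled out after their values were seen, together took 7.29% to 7.47% of summed FPKM with 15d-PGJ2 and 4.83% to 4.98% in controls.

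Markers of other blood cells were not called as lists. Of 8 neutrophil markers Mpo rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.103), and the list passed with a filter of 5 FPKM (0.0322, range 0.0322 to 0.145). Batf3 fell among 3 dendritic markers (camera adjusted p = 0.52). Of 7 osteoclast markers Itgb3 rose and Acp5, Mmp9 and Nfatc1 fell (camera adjusted p = 0.393), and of 3 endothelial markers Vwf and Esam rose and Pecam1 fell (camera adjusted p = 0.646). Score intervals excluded 0 for neutrophil markers (-0.35, 95% interval -0.45 to -0.25), dendritic markers (-0.20, -0.30 to -0.09) and endothelial markers (0.40, 0.16 to 0.64). B cell markers, with 2 tested members, summed to 137 to 141 FPKM per library in controls and 74.4 to 78.3 with 15d-PGJ2. T and NK cell markers summed to 2.26 to 4.23 FPKM per library and mast cell markers to 0.39 to 1.45, over all groups. Of the 16 called lists, Nrf2 targets, interferon-γ response, endoplasmic reticulum genes, the proteasome and stromal markers kept their calls with an estimated correlation (adjusted p = 0.00185, 0.0488, 0.0488, 0.0488 and 0.0488). The stromal call may reflect RNA of another tissue in the controls, which was not settled.

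With 15d-PGJ2-PC, 28 of 30 Nrf2 targets, 20 of 21 heat shock genes and 30 of 31 proteasome genes rose against control, and 29 of 31 type I interferon-induced genes, 9 of 18 endoplasmic reticulum genes and 13 of 18 macrophage markers fell. With an estimated correlation the list calls were lost for heat shock and interferon-induced genes (adjusted p = 0.104 each) and for endoplasmic reticulum genes and macrophage markers (0.115 each). Hmox1 rose from 332 ± 8.11 to 2781 ± 54.2 FPKM (SD, n = 3 per group), an 8.35-fold change (log2 3.06, SE 0.03, adjusted p = 3.88e-13). Hspa1b rose to 207 ± 30.0 FPKM, Psma5 to 150.1 ± 1.35, and Ifit3 fell to 99.4 ± 8.55. Limma called 3147 genes (27.8%): 1556 rose, 119 at least 2-fold, and 1591 fell, 107 at least 2-fold. Groups did not overlap for 4725 genes (41.8%), where chance gives 10%.

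Nrf2 targets rose in 28 of 30 cases, Ugdh fell and Ephx1 did not pass, the same adjusted over the list alone (median 0.93, camera adjusted p = 8.56e-30). Srxn1 reached 276 FPKM, Gclm 270 ± 5.53 and Txnrd1 293, with log2 changes of 2.15, 2.09 and 1.57, and Slc7a11 and Nqo1 rose by 0.42 and 0.83. Heat shock genes rose in 20 of 21 cases, 1 not passing (21 adjusted over the list alone, median 1.08, camera adjusted p = 2.72e-21, adjusted p = 0.104 with an estimated correlation). The member not passing was Hspa4 (adjusted p = 0.0619), which passed without control replicate 3 (0.0224) or 15d-PGJ2 replicate 1 (0.0473, range 0.0224 to 0.199 over the libraries left out). Hspa1b rose by 5.25, Hspa1a by 4.67, Hspa8 by 1.10 and the co-chaperone gene Dnajb4 from 5.57 to 25.0 FPKM. Of 31 proteasome genes all but Psma6 rose, also adjusted over the list alone (median 0.73, camera adjusted p = 7.9e-27). Psma5, Psmd11, Psma7 and Psmd2 rose by 1.08, 1.09, 0.88 and 0.73. Cdkn2b (15.1 FPKM) and the stress kinase gene Plk3 (1.81 to 8.63 FPKM) were among the largest rises. Nfe2l2 was at 76.5 FPKM (adjusted p = 0.78).

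Type I interferon-induced genes fell in 29 of 31 cases, with Isg20 and Oasl1 not passing (30 adjusted over the list alone, median -0.79, camera adjusted p = 6.83e-22, adjusted p = 0.104 with an estimated correlation). Oasl1 (adjusted p = 0.0511) passed without 15d-PGJ2 replicates 1 or 2 (0.0319 and 0.0413) or 15d-PGJ2-PC replicate 3 (0.0413, range 0.0319 to 0.171). Ifit3, Ifit2, Cmpk2 and Stat2 fell by 1.76, 1.63, 1.75 and 1.10 on the log2 scale. Of 15 interferon-γ response genes 10 fell (11 adjusted over the list alone, median -0.40, camera adjusted p = 1.07e-06, adjusted p = 0.0541 with an estimated correlation). Iigp1 fell to 4.53 ± 0.74 FPKM and Tap1 by 0.51 on the log2 scale. Endoplasmic reticulum genes fell in 9 of 18 cases and Edem1 rose (10 and 1 adjusted over the list alone, median -0.13, camera adjusted p = 0.000212, adjusted p = 0.115 with an estimated correlation). Edem1 (adjusted p = 0.0372) did not pass without control replicates 1 or 2 (0.114 and 0.0865), 15d-PGJ2-PC replicates 1 or 2 (0.104 and 0.113) or 15d-PGJ2 replicate 2 (0.0507, range 0.0281 to 0.114). Pdia6, Calr and Herpud1 fell by 0.36, 0.37 and 0.37.

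The ATF4 list had 12 genes that rose, 9 that did not pass and 2 that fell, Ddit4 and Aldh18a1, the same adjusted over the list alone (median 0.22, camera adjusted p = 0.000176, adjusted p = 0.201 with an estimated correlation). Aldh18a1 (adjusted p = 0.0365) did not pass without control replicates 1, 2 or 3 (0.0967, 0.0662 and 0.0841) or 15d-PGJ2-PC replicates 2 or 3 (0.118 and 0.0969, range 0.0298 to 0.118). Slc3a2 rose by 0.88, Atf4 by 0.52, Trib3 by 0.77 and Ddit3, which encodes CHOP, by 0.35. Glycolysis and hypoxia genes rose in 10 of 21 cases, and Hk2, Ldha and Ndrg1 fell (12 and 3 adjusted over the list alone, median 0.10, camera adjusted p = 0.00841, adjusted p = 0.132 with an estimated correlation). Slc2a1 and Pkm rose by 1.17 and 0.59.

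Cholesterol synthesis genes fell in 9 of 23 cases and rose in 1 (10 and 1 adjusted over the list alone, median -0.14, camera adjusted p = 0.0349, adjusted p = 0.203 with an estimated correlation). The call was lost with a filter of 5 FPKM (0.389) and without 15d-PGJ2-PC replicate 3 (0.0536, range 0.0183 to 0.389). Without 15d-PGJ2-PC replicate 2, 5 cholesterol synthesis genes fell. Idi1 fell by 0.83. Of 28 cell cycle genes 5 fell, E2f1 by 0.30 and Mcm6 by 0.28 among them (2 adjusted over the list alone, median -0.19, camera adjusted p = 0.0358, adjusted p = 0.203 with an estimated correlation). This call was lost with a filter of 5 FPKM (0.158) and without control replicate 1 (0.0628), 15d-PGJ2-PC replicate 2 (0.0612) or 15d-PGJ2-PC replicate 3 (0.0769, range 0.0123 to 0.158). The 5 fallen cell cycle genes became 2 without control replicates 1 or 2 or 15d-PGJ2-PC replicate 3. LXR targets were not called (2 of 15 rose and 5 fell, 2 and 6 adjusted over the list alone, camera adjusted p = 0.104) except without control replicate 3 (0.0382, range 0.0382 to 0.217). Their score differed by -0.15 (95% interval -0.23 to -0.06, excluding 0), and 1 rose without control replicates 2 or 3 or 15d-PGJ2-PC replicate 1. Abca1 fell by 0.48 and Nr1h3 by 0.35.

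PPAR targets were not called with 15d-PGJ2-PC (5 of 21 rose and 3 fell, 7 and 3 adjusted over the list alone, camera adjusted p = 0.147), with a score difference of 0.09 (95% interval 0.05 to 0.13) that excludes 0. Acadvl rose by 0.69 and Cd36 by 0.30, and Fabp4 did not pass (adjusted p = 0.831). Plin2 fell by 0.14, a call lost without the trend (0.0716, range 0.00463 to 0.0716). Angptl4 rose by 0.32 (adjusted p = 0.0136), though not without control replicate 2 (0.053, range 0.00943 to 0.053). Pparg did not pass (0.175) except without 15d-PGJ2-PC replicate 3 (0.0394, range 0.0394 to 0.506). Metallothionein genes Mt1 and Mt2, which bind metals, rose by 0.17 and 0.29 (adjusted p = 0.00751 and 7.05e-05).

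Genes of NF-κB-driven inflammation were again not called (4 of 25 rose and 8 fell, 6 and 9 adjusted over the list alone, camera adjusted p = 0.435). Cxcl2 rose to 12.1 FPKM and Il1b fell by 0.64, while Tnf and Il6 did not pass (adjusted p = 0.477 and 0.784). Alternative activation genes (1 of 9 rose and 3 fell, also adjusted over the list alone, camera adjusted p = 0.214) included Il10, which fell by 1.07, and eicosanoid genes (6 of 16 rose and Ptgs1 fell, also adjusted over the list alone, camera adjusted p = 0.11) included Ptgr1, which rose by 1.19. Phospholipid genes were not called (6 of 25 rose and 6 fell, also adjusted over the list alone, camera adjusted p = 0.741), and among them the phospholipase genes Pla2g7 and Pla2g6 rose by 0.34 and 0.64. Immediate early genes (3 of 14 rose and 5 fell, 4 and 5 adjusted over the list alone, median -0.27, camera adjusted p = 0.271) included Btg2, which fell by 0.78. Lysosome and autophagy genes rose in 10 of 23 cases and fell in 3, also adjusted over the list alone (camera adjusted p = 0.057). That list passed with no filter (0.0237) and without control replicates 1 or 2 (0.0266 and 0.0472) or 15d-PGJ2-PC replicate 3 (0.0332, range 0.0237 to 0.155). Of 26 oxidative phosphorylation genes 5 fell, also adjusted over the list alone (camera adjusted p = 0.0501), among them Ndufb3 by 0.41. This list passed without control replicate 3 (0.0155), 15d-PGJ2-PC replicate 1 (0.0267) or 15d-PGJ2 replicate 1 (0.0453), and with median-of-ratios scaling, no filter or a pseudocount of 0.1 (0.0446, 0.0455 and 0.0458, range 0.0155 to 0.177). The 5 fallen genes became 2 without control replicate 1 and 3 without control replicate 2 or 15d-PGJ2-PC replicates 2 or 3. Lysosome genes that rose numbered 6 without control replicate 2 or 15d-PGJ2-PC replicate 1, and 1 fell without control replicates 1 or 2 or 15d-PGJ2-PC replicate 2. Without 15d-PGJ2-PC replicate 2, 3 eicosanoid genes rose, and without control replicate 2 or 15d-PGJ2-PC replicate 3, 2 NF-κB-driven genes. Score intervals excluded 0 for alternative activation genes (-0.25, 95% interval -0.38 to -0.12), eicosanoid genes (0.16, 0.09 to 0.24) and immediate early genes (-0.18, -0.26 to -0.09). So did those of lysosome genes (0.13, 0.07 to 0.18) and oxidative phosphorylation genes (-0.08, -0.13 to -0.03).

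Macrophage markers fell in 13 of 18 cases (14 adjusted over the list alone, median -0.25, camera adjusted p = 1.46e-07, adjusted p = 0.115 with an estimated correlation). All 7 stromal markers fell, also adjusted over the list alone (median -1.61, camera adjusted p = 6.83e-08), to a summed 11.9 ± 0.47 FPKM. The erythroid genes Hba-a1, Hbb-bs and Hbb-bt fell and Pf4 did not pass, the same adjusted over the list alone (median -2.13, camera adjusted p = 0.0138, adjusted p = 0.112 with an estimated correlation). The 10 largest falls taken by the naming rule were from 3.52 to 16.4 FPKM in controls to near 0: Hba-a1, H19 (0.34 FPKM), Col3a1 (7.12 to 0.11), Igf2 (5.65 to 0.07), Actg2 and Hbb-bs, and 4 genes listed at 0 in every treated library. These were Lor, the elastin gene Eln (5.33 ± 0.93 in controls) and the keratin genes Krt1 (3.88 ± 0.75, Entrez 16678, chromosome 15, 101845426 to 101850786) and Krt71 (3.52 ± 0.53, Entrez 56735, chromosome 15, 101733949 to 101743097). For these largest falls, RNA of another tissue in the controls is a candidate explanation, as with 15d-PGJ2. Without the genes seen in controls only, 3106 genes changed. Of the fallen genes, 614 had a control mean under 20 FPKM and 977 lay above it. Structural noncoding RNAs rose in 5 of 9 cases (7 adjusted over the list alone, median 0.42, camera adjusted p = 0.00128, adjusted p = 0.0619 with an estimated correlation). Fth1 and Ftl1 took 5.96% to 6.02% of summed FPKM.

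The histone list was not called with 15d-PGJ2-PC (1 of 8 fell, camera adjusted p = 0.324). Neither were neutrophil markers (1 of 8 rose and 2 fell, 0.302), dendritic markers (Batf3 fell, 0.324), osteoclast markers (Mmp9 and Nfatc1 fell, 0.316) or endothelial markers (0 of 3 passed, 0.856). The score interval excluded 0 for dendritic markers (-0.16, 95% interval -0.27 to -0.06). Without control replicates 1 or 3 or 15d-PGJ2-PC replicate 1 no histone gene fell. Without these 1, 1 and 2 histone genes rose, and 1 rose without 15d-PGJ2-PC replicate 2. Without control replicate 3 or 15d-PGJ2-PC replicate 1, 1 neutrophil marker fell, and 1 endothelial marker fell without 15d-PGJ2-PC replicate 2. B cell markers summed to 99.5 to 106 FPKM per library. None of 29 ribosomal protein genes passed (1 rose without control replicate 1), and the list was not called (0.057). It passed with no filter (0.0237), without control replicates 1 or 2 (0.00299 and 0.0196) and without 15d-PGJ2-PC replicate 3 (0.0455, range 0.00299 to 0.81). Of the 14 called lists, Nrf2 targets, the proteasome and stromal markers held with an estimated correlation (adjusted p = 0.000996, 0.0388 and 0.019). As with 15d-PGJ2, RNA of another tissue in the controls may lie behind the stromal call.

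**Figure D2:**
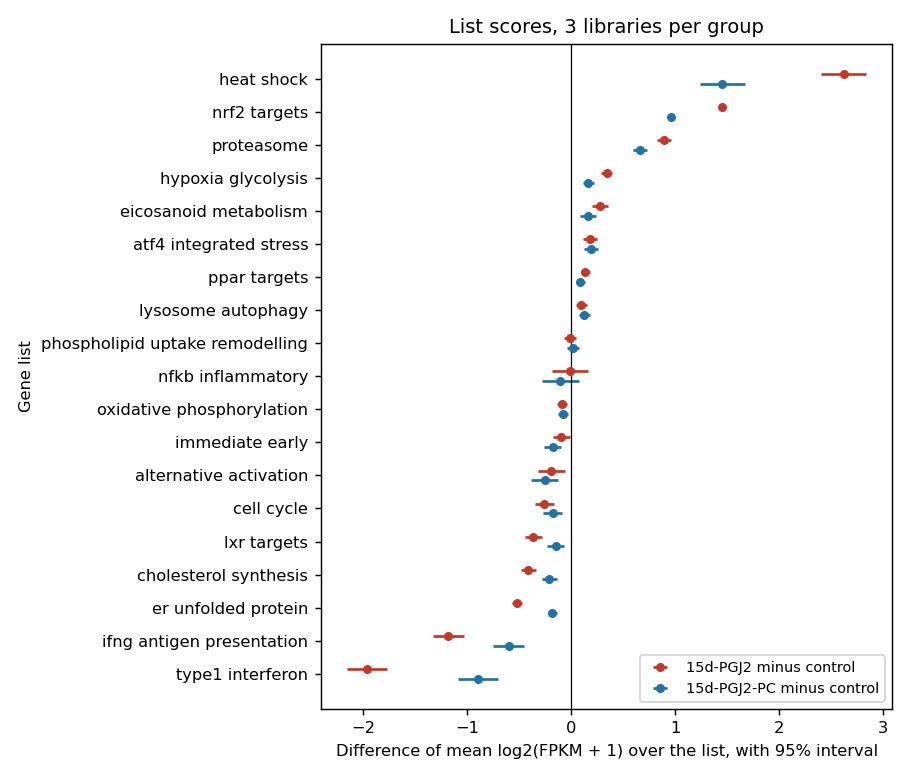
Difference of list scores (mean log2(FPKM + 1) over a list's tested genes) from control for 15d-PGJ2 and 15d-PGJ2-PC over the 19 pathway lists; points are differences and lines 95% intervals, with 3 libraries per group. Heat shock, Nrf2 and proteasome lists lie above 0 and interferon lists below it for both compounds, farther out for 15d-PGJ2.

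Compared directly at 1 µM and 6 h, 15d-PGJ2-PC gave lower levels than 15d-PGJ2 of 20 of 21 heat shock genes, 28 of 30 Nrf2 targets and 24 of 31 proteasome genes, and higher levels of 28 of 31 type I interferon-induced and 16 of 18 endoplasmic reticulum genes. With an estimated correlation the list calls of heat shock, proteasome and interferon-induced genes were lost (adjusted p = 0.0604 each). Hmox1 was at 2781 ± 54.2 FPKM with 15d-PGJ2-PC and 6540.1 ± 124 with 15d-PGJ2 (SD, n = 3 per group, log2 difference -1.23, SE 0.03, adjusted p = 4.5e-09). Hspb1 was at 17.4 ± 3.96 against 186 ± 43.8 FPKM, and Ifit3 at 99.4 ± 8.55 against 19.5 ± 1.00. Limma called 2335 genes (20.6%): 1396 were higher with 15d-PGJ2-PC, 65 at least 2-fold, and 939 lower, 54 at least 2-fold. Groups did not overlap for 4214 genes (37.3%), where chance gives 10%.

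Of 21 heat shock genes, 20 were lower with 15d-PGJ2-PC (21 adjusted over the list alone, median -0.92, camera adjusted p = 1.23e-26, adjusted p = 0.0604 with an estimated correlation). Hspb1 differed by -3.34 (SE 0.20) on the log2 scale, Hsp90aa1 by -1.42 (280.1 against 756 FPKM) and Hspa8 by -0.74, and Hspa1b was at 207 against 837 FPKM. The unlogged score of the list with 15d-PGJ2-PC was 0.45 of that with 15d-PGJ2 (95% interval 0.38 to 0.52 on the FPKM + 1 scale). Of 30 Nrf2 targets 28 were lower and Ugdh was higher, also adjusted over the list alone (median -0.42, camera adjusted p = 1.71e-27). Their unlogged score was 0.71 (0.70 to 0.73) of that with 15d-PGJ2. Gclm, Srxn1 and Txnrd1 differed by -0.85, -0.70 and -0.44, Slc7a11 by -0.75 and Nqo1 by -1.09. Of 31 proteasome genes 24 were lower (27 adjusted over the list alone, median -0.23, camera adjusted p = 4.4e-15, adjusted p = 0.0604 with an estimated correlation), including Psmd14 by -0.44 and Psma7 by -0.28. The unlogged proteasome score was 0.85 (0.81 to 0.89) of that with 15d-PGJ2. Glycolysis and hypoxia genes were lower in 11 of 21 cases, and Tpi1 and Ldha were higher (12 and 3 adjusted over the list alone, median -0.17, camera adjusted p = 4.52e-05, adjusted p = 0.0604 with an estimated correlation). Pkm was at -0.35 and the hydroxylase gene P4ha1 at -0.63, and the unlogged list score was 0.88 (0.85 to 0.92) of that with 15d-PGJ2.

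Type I interferon-induced genes were higher with 15d-PGJ2-PC in 28 of 31 cases (29 adjusted over the list alone, median 1.09, camera adjusted p = 1.71e-27, adjusted p = 0.0604 with an estimated correlation). Ifit3 differed by 2.29 (SE 0.09), Ifit2 by 2.20 and Rtp4 by 1.37. The unlogged list score was 2.10 times (1.83 to 2.40) that with 15d-PGJ2. Of 15 interferon-γ response genes 9 were higher (10 adjusted over the list alone, median 0.40, camera adjusted p = 1.38e-06, adjusted p = 0.0604 with an estimated correlation). Gbp2 was higher by 1.12 and Iigp1 was at 4.53 against 0.47 FPKM, and the unlogged score was 1.49 times (1.35 to 1.65) as high. Abcg3 (10.5 against 2.18 FPKM) and the schlafen gene Slfn5 (41.5 against 12.4) were other large differences, with the antisense gene Slfn5os listed at 0 in every 15d-PGJ2 library and at a mean of 1.98 FPKM with 15d-PGJ2-PC.

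Endoplasmic reticulum genes were higher in 16 of 18 cases, also adjusted over the list alone (median 0.33, camera adjusted p = 1.5e-11). Their unlogged score was 1.27 times (1.23 to 1.31) as high. Hspa5 differed by 0.58, Hyou1 by 0.59 and Pdia4 by 0.54. LXR targets were higher in 6 of 15 cases (7 adjusted over the list alone, median 0.12, camera adjusted p = 0.00346, adjusted p = 0.181 with an estimated correlation). Their unlogged score was 1.16 times (1.10 to 1.23) as high. Nr1h3 differed by 0.83 and Abca1 by 0.57. Cholesterol synthesis genes were higher in 5 of 23 cases and lower in 1, also adjusted over the list alone (median 0.19, camera adjusted p = 0.0205, adjusted p = 0.181 with an estimated correlation). The unlogged score was 1.15 times (1.09 to 1.21) as high. This call was lost with a filter of 5 FPKM (0.0638) and without 15d-PGJ2 replicate 3 (0.0678, range 0.00966 to 0.0678). The 5 higher genes became 2 without 15d-PGJ2 replicate 3 and 3 without control replicates 1 or 2 or 15d-PGJ2-PC replicates 1 or 3.

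Several lists were not called between the compounds, and their score intervals bound the difference on the log2 scale. The ATF4 list differed by 0.01 (95% interval -0.05 to 0.08, camera adjusted p = 0.623), with 2 of 23 genes higher and 4 lower (3 and 4 adjusted over the list alone) and a median of -0.002. Aars, an aminoacyl-tRNA synthetase gene, differed by -0.26 and Ddit4 by 0.68. Oxidative phosphorylation genes differed by 0.01 (-0.04 to 0.05, adjusted p = 0.937), with 3 of 26 higher and Ndufb8 lower, also adjusted over the list alone. Phospholipid genes differed by 0.03 (-0.03 to 0.09, adjusted p = 0.819), with 6 of 25 higher and 3 lower (7 and 3 adjusted over the list alone), among them Pld4 at 0.50 and Marco at -0.28. NF-κB-driven genes differed by -0.10 (-0.27 to 0.08, adjusted p = 0.832, median 0.001), with 4 of 25 higher and 6 lower (5 and 7 adjusted over the list alone). Cxcl2 differed by -1.35 and Il12b by 1.31, while Il1b and Tnf did not pass (adjusted p = 0.995 and 0.929). Il6 differed by -0.70 (adjusted p = 0.0329), though not without 15d-PGJ2 replicates 2 or 3 (0.105 and 0.0912), 15d-PGJ2-PC replicates 1 or 3 (0.0608 and 0.102) or with a pseudocount of 0.1 (0.0564, range 0.0253 to 0.105). Without 15d-PGJ2 replicates 2 or 3 or 15d-PGJ2-PC replicate 1, 3 NF-κB-driven genes were lower. Without 15d-PGJ2 replicates 1 or 2 or 15d-PGJ2-PC replicates 1 or 3, 1 ATF4 list gene was higher. Oxidative phosphorylation genes had 1 higher without 15d-PGJ2 replicates 2 or 3 or 15d-PGJ2-PC replicate 2, and 2 lower without control replicate 3.

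No cell cycle gene passed between the compounds (1 was higher without 15d-PGJ2-PC replicate 3), and the list differed by 0.08 (-0.01 to 0.17, camera adjusted p = 0.623). Lysosome genes differed by 0.03 (-0.03 to 0.08, adjusted p = 0.579), with 7 of 23 higher and 3 lower (8 and 4 adjusted over the list alone) and Gabarapl1 at -0.47. Alternative activation genes differed by -0.06 (-0.19 to 0.07, adjusted p = 0.376), with 1 of 9 higher (1 higher and 4 lower adjusted over the list alone). Immediate early genes differed by -0.08 (-0.17 to 0.001, adjusted p = 0.376), with 1 of 14 higher and 3 lower (2 and 4 adjusted over the list alone) and the phosphatase gene Dusp1 at -0.46. PPAR targets differed by -0.05 (-0.09 to -0.01, an interval that excludes 0) and were not called (1 of 21 higher and 4 lower, 2 and 5 adjusted over the list alone, camera adjusted p = 0.376), with Acadl at -0.34. Eicosanoid genes differed by -0.12 (-0.19 to -0.04, also excluding 0) and were not called (2 of 16 higher and 5 lower, 2 and 6 adjusted over the list alone, camera adjusted p = 0.0808), with Ptgr1 at -1.05 and Abcc4 at -0.75. That list passed without 15d-PGJ2 replicate 2 (0.0388) or 15d-PGJ2-PC replicate 3 (0.0497, range 0.0388 to 0.162). Without 15d-PGJ2 replicate 2, 4 lysosome genes were higher. No alternative activation gene was higher without 15d-PGJ2-PC replicates 1 or 2, and 1 was lower without control replicate 3 or 15d-PGJ2 replicate 3. No immediate early gene was higher without control replicate 2, 15d-PGJ2 replicates 1 or 3 or any 15d-PGJ2-PC replicate. PPAR targets had 2 higher without replicate 3 of any group and none without any other library.

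Of the fixed genes, Nfe2l2, Fabp4, Pparg and Angptl4 did not differ between the compounds past the threshold (adjusted p = 0.577, 0.624, 0.348 and 0.534). Mt2 was higher with 15d-PGJ2-PC by 0.18 (0.00264). Mt1 differed by 0.11 (0.0903), passing without 15d-PGJ2-PC replicate 3 (0.0482) and with quantile normalization (0.0037, range 0.0037 to 0.274), and Cd36 by -0.08 (0.167), passing without 15d-PGJ2-PC replicate 1 (0.0428, range 0.0428 to 0.982). Plin2 differed by 0.10 (0.0532) and passed without control replicate 3 (0.0495), 15d-PGJ2 replicate 3 (0.0275) or 15d-PGJ2-PC replicate 3 (0.0325), within a range of 0.0219 to 0.198.

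Macrophage markers were higher with 15d-PGJ2-PC in 16 of 18 cases (17 adjusted over the list alone, median 0.29, camera adjusted p = 1.74e-11, adjusted p = 0.0604 with an estimated correlation). Stromal markers were not called (1 of 7 lower, score difference -0.19, 95% interval -0.31 to -0.07, camera adjusted p = 0.155), nor were erythroid markers (0 of 4 passed, 0.883) or neutrophil markers (2 of 8 higher, score difference 0.32, 0.21 to 0.42, camera adjusted p = 0.0808). Dendritic markers (1 of 3 higher, 0.828), osteoclast markers (2 of 7 higher and 1 lower, 0.509) and endothelial markers (Pecam1 higher and Esam lower, score difference -0.29, -0.53 to -0.05, camera adjusted p = 0.679) were not called either. Neutrophil markers had 1 higher without 15d-PGJ2 replicate 3 or 15d-PGJ2-PC replicates 2 or 3. No stromal marker was lower without 15d-PGJ2 replicates 1 or 3 or any 15d-PGJ2-PC replicate. No dendritic marker was higher without 15d-PGJ2 replicates 1 or 2 or 15d-PGJ2-PC replicates 2 or 3, and no osteoclast marker lower without replicates 2 or 3 of either compound. Ribosomal protein genes were lower as a list, with Rps2 and Rpsa passing over all genes and none adjusted over the list alone (median -0.07, camera adjusted p = 0.000196, adjusted p = 0.451 with an estimated correlation). The score interval included 0 (-0.16 to 0.01), and 13 genes were lower without control replicate 3, none without 15d-PGJ2 replicate 2, 2 without control replicate 1 and 1 without any other library. Rps2 (adjusted p = 0.0401) did not pass without 15d-PGJ2 replicates 1, 2 or 3 (0.117, 0.0887 and 0.0631), 15d-PGJ2-PC replicates 1, 2 or 3 (0.0725, 0.125 and 0.0805) or control replicate 2 (0.0543, range 0.00276 to 0.125). Rpsa (0.0232) did not pass without 15d-PGJ2 replicates 1 or 2 (0.0675 and 0.0738) or 15d-PGJ2-PC replicates 1 or 3 (0.0507 and 0.0812, range 0.00297 to 0.0812).

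Histones were lower in 6 of 8 cases, also adjusted over the list alone (median -0.78, camera adjusted p = 0.000146, adjusted p = 0.0706 with an estimated correlation), alongside the heat shock genes. Of single histone genes, Hist2h3c2 passed (adjusted p = 0.0239) but not without 15d-PGJ2 replicates 2 or 3 (0.065 and 0.0709) or 15d-PGJ2-PC replicates 2 or 3 (0.0886 and 0.0832). Its call was also lost without the trend (0.0504), with no filter (0.0521), with the 6 libraries of the contrast alone (0.0732) and with robust priors (0.0948, range 9.69e-07 to 0.0948). Hist1h2bj passed (0.0202) but not without 15d-PGJ2 replicate 3 (0.0779) or 15d-PGJ2-PC replicates 2 or 3 (0.078 and 0.0735). The 6 libraries of the contrast alone (0.0507) and robust priors (0.0781) also ended the Hist1h2bj call (range 0.000697 to 0.0781). The small nuclear RNA gene Rnu1a1 was at 0.46 FPKM with 15d-PGJ2-PC and 6.50 with 15d-PGJ2, and Hist1h2bq and Hist1h2br, which carry identical values, at 1.81 and 10.3. Structural noncoding RNAs were lower in 3 of 9 cases (Rn45s, Rpph1 and Rn7sk) and Neat1 was higher, also adjusted over the list alone (median -0.14, camera adjusted p = 0.0336, adjusted p = 0.13 with an estimated correlation). That call was lost without 15d-PGJ2 replicate 3 (0.0564) and with quantile normalization (0.0567, range 0.00832 to 0.0567). Of the 13 called lists, Nrf2 targets and endoplasmic reticulum genes held with an estimated correlation (adjusted p = 0.00129 and 0.0495).

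Across the tested genes, which are not independent replicates, the log2 responses to the compounds correlated at 0.849 (Pearson, jackknife SE 0.0057, Spearman 0.828), and 82.6% had the same sign. Unchanged groups simulated against the same controls gave 0.499 and 66.7%. The covariance was 0.172 against 0.0143 simulated, a difference of 0.158. Of the genes called, 1394 rose in both contrasts, where independent lists would share 346, and 1496 fell in both, where they would share 397. Genes called in opposite directions numbered 9, where independent lists would give 354 and 388: 3 rose with 15d-PGJ2 and fell with 15d-PGJ2-PC (Gja1, Sun2 and Atp1b3, named for their opposite calls), and 6 did the reverse. None of the 9 kept both calls with each library left out in turn. Part of the excess may come from the shared controls, since 3 are too few to be divided into 2 sets of 2.

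On the log2 scale, the size of the 15d-PGJ2-PC response relative to that of 15d-PGJ2 differed between gene groups. The ratio of score changes was 0.743 for the proteasome (SE 0.029), 0.664 for Nrf2 targets (SE 0.009), 0.555 for heat shock genes (SE 0.025), 0.455 for type I interferon genes (SE 0.032) and 0.345 for endoplasmic reticulum genes (SE 0.026). The heat shock ratio differed from that of the proteasome by -0.188 (SE 0.020) and the type I interferon ratio by -0.288 (SE 0.046). It was 1.06 for the ATF4 list (SE 0.169) and 1.13 for stromal markers (SE 0.040). The order of the lists depends on the scale. As median fractions of the 15d-PGJ2 change in FPKM, heat shock genes (0.337) lay below type I interferon genes (0.628). Of the 2515 genes that rose with 15d-PGJ2, 864 were lower with 15d-PGJ2-PC, 8 were higher and 1643 did not differ past the threshold. Of the 2823 that fell, 1288 were higher, 4 lower and 1531 did not differ past it. Beyond the 15d-PGJ2 level in the direct comparison lay 58 genes that rose and 24 that fell against control with 15d-PGJ2-PC, 82 in all, where simulations of no such difference gave a median of 29 and at most 43. Among these, chosen after their values were seen, were Slc30a1, a zinc exporter gene (26.2 in controls, 29.9 with 15d-PGJ2 and 35.9 FPKM with 15d-PGJ2-PC), and on the falling side Arrdc3 (16.8, 14.0 and 7.90 FPKM).

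**Figure D3:**
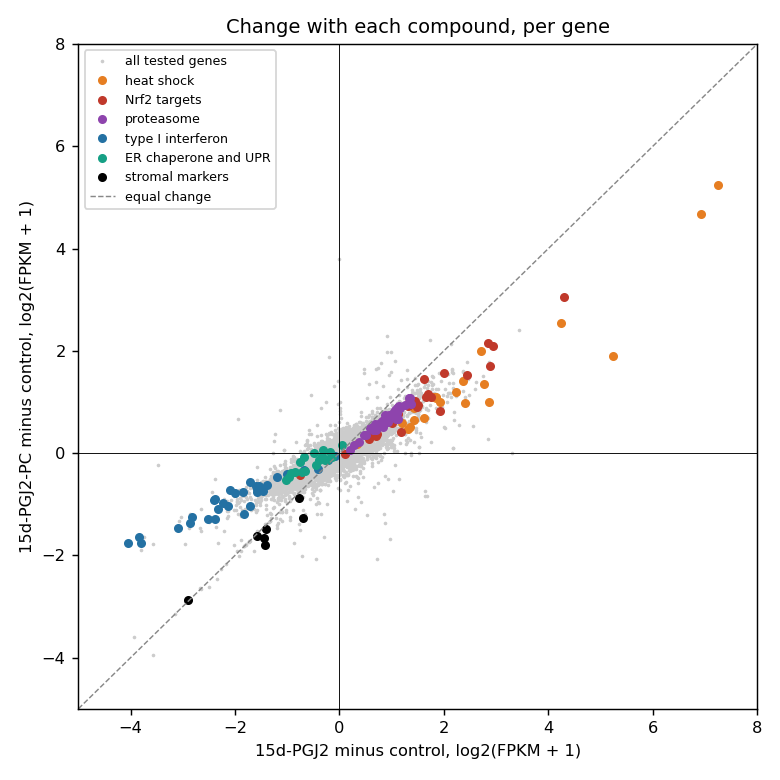
Log2 fold change with 15d-PGJ2-PC against that with 15d-PGJ2 for the 11309 tested genes, both against the same 3 controls; the dashed line marks equal change and colours mark 6 gene lists. Most genes of the heat shock, Nrf2 and interferon lists lie between the dashed line and no change with 15d-PGJ2-PC, and stromal markers lie along the line.

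**Figure D4:**
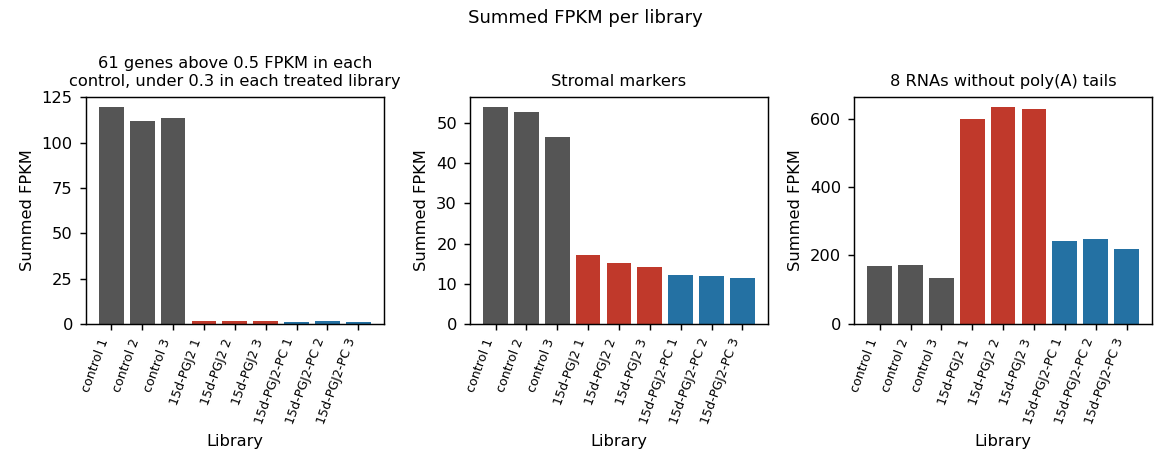
Summed FPKM in each of the 9 libraries (bars, from 0) of the 61 genes seen in controls only, 13 stromal markers and 8 RNAs without poly(A) tails. The 61 genes sum to 115 ± 3.86 FPKM in controls and to under 2 in treated libraries, and the 8 RNAs to 620 ± 17.8 with 15d-PGJ2.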

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

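The 9 genes below were chosen after their values were seen, because the compounds moved them to opposite sides of control and the direct test of the difference between the compounds passed. Gja1, which encodes the gap junction protein connexin 43, had 3.64 FPKM in controls, 5.09 with 15d-PGJ2 and 2.54 with 15d-PGJ2-PC. Its log2 difference between the compounds was -0.775 (15d-PGJ2-PC minus 15d-PGJ2, SE 0.116, limma adjusted p = 0.000856). Sun2, a nuclear envelope gene, differed by -0.305 (57.0 against 70.6 FPKM, control 66.0, adjusted p = 0.000159). Atp1b3, a sodium pump subunit gene, differed by -0.304 (103 against 127 FPKM, control 114.7, adjusted p = 0.000668).

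The other 6 genes were higher than control with 15d-PGJ2-PC and lower with 15d-PGJ2. Cd200r1, an inhibitory receptor gene of myeloid cells, differed by 0.68 (36.7 against 22.5 FPKM, control 32.0, adjusted p = 3.32e-05), and the myelin protein gene Pmp22 by 0.57 (43.3 against 28.9 FPKM, adjusted p = 0.000189). Aph1c, a γ-secretase subunit gene, differed by 0.486 (adjusted p = 0.000548), the inflammasome gene Nlrp1b by 0.413 (0.000547), the cholesterol ester hydrolase gene Nceh1 by 0.364 (0.000287) and Rasa4 by 0.312 (7.12e-05). The direct difference passed for all 9 with each of the 9 libraries left out in turn (highest adjusted p = 0.00496). None of the 9 kept both of its calls against control in that way. Leaving out single libraries ended the 15d-PGJ2 call of Sun2 in 7 of 9 cases (adjusted p up to 0.106) and those of Gja1, Atp1b3 and Aph1c in 2 each (up to 0.0734, 0.0668 and 0.0628). It ended the 15d-PGJ2-PC call of Gja1 in 4 cases (up to 0.0954), Atp1b3 in 2 (0.0844) and Aph1c in 3 (0.0663). The 15d-PGJ2-PC call also ended for Rasa4 in 8 cases (up to 0.128), Cd200r1 in 6 (0.143), Nlrp1b in 5 (0.102), Nceh1 in 4 (0.11) and Pmp22 in 3 (0.0968).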

How the results depend on the processing

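The alternatives with genes of at least 20 FPKM on average and without the genes seen in controls only were chosen after the result was seen. No gene named under the naming rule and no list that was called as reported changed direction under any alternative, nor did the correlation. Some that were not called did, such as Fabp4, Tnf and Il6 and the medians of the PPAR, ATF4 and NF-kB lists between the compounds. With quantile normalization 5095 of the 5096 genes called with 15d-PGJ2 in both ways kept their direction, and the balance turned from 2515 that rose and 2823 that fell to 2713 and 2635. For 15d-PGJ2-PC against control it turned from 1556 and 1591 to 1596 and 1549 with quantile normalization, 1520 and 1456 with a filter of 5 FPKM, 1568 and 1558 with a pseudocount of 0.1 and 1470 and 1466 without the trend. It also turned without control replicate 2 (1307 and 1269) or 3 (1394 and 1386). With genes of at least 20 FPKM, 2421, 1768 and 1487 genes changed (15d-PGJ2 against control, 15d-PGJ2-PC against control and the compounds against each other), fewer because fewer genes were tested. A minimum change of 1.5-fold, which can only lower a count, left 1944, 760 and 483. With an estimated correlation camera called 5, 3 and 2 lists, and fry, which asks another question, called 25 and 24 lists against control. Without the genes seen in controls only the counts were 5303, 3106 and 2329.

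The correlation of the responses to the compounds was 0.796 with a pseudocount of 0.1, 0.836 with no filter and 0.882 with a filter of 5 FPKM. The cause was not tested. With each library left out in turn it ran from 0.824 to 0.855, genes changed from 4732 to 5291, 2576 to 3144 and 1791 to 2373, and lists from 15 to 17, 13 to 16 and 11 to 14. The replicate number as a block gave 5272, 3041 and 2215 genes, of which 5114, 2901 and 2100 were called without it, all in the same direction. The block also called ribosomal protein genes with 15d-PGJ2-PC (camera adjusted p = 0.0337, range 0.00299 to 0.81). Library pairs of the same number correlated at -0.043 to 0.052 after group means were removed, against -0.07 to 0.098 for other pairs, so the numbers were not treated as pairs. With median-of-ratios scaling the share of differing genes that were higher with 15d-PGJ2-PC was 53.4%, and 52.7% with quantile normalization, against 59.8% as reported. Over all alternatives, calls of named genes were kept in 6005 cases and lost in 81 (20 results). Results not called stayed so in 532 cases and gained a call in 21 (8 results). Under the other camera settings list calls were kept in 628 cases and lost in 15, and lists not called stayed so in 631 and gained a call in 22. An estimated correlation ended 33 list calls, and fry added 23 and ended 1.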

Other observations

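Gene families formed from gene descriptions, 29 in all, were chosen and tested after the data were seen, and each called family lost its call with an estimated correlation. All 6 guanylate binding protein genes, GTPases of cell-autonomous immunity, fell with 15d-PGJ2 (median -2.11, camera adjusted p = 4.65e-05, adjusted p = 0.181 with an estimated correlation). Gbp6 was at 20.5, 3.59 and 10.3 FPKM in control, 15d-PGJ2 and 15d-PGJ2-PC libraries, and Gbp7 at 10.7, 1.65 and 4.30. All 6 also fell with 15d-PGJ2-PC (median -0.92, adjusted p = 4.19e-05, 0.264 with an estimated correlation) and were higher with it than with 15d-PGJ2 (median 1.06, adjusted p = 6.28e-06, 0.15 with an estimated correlation). Of 9 schlafen genes 8 fell with 15d-PGJ2 (median -1.88, adjusted p = 3.63e-05, 0.181 with an estimated correlation), with Slfn8 at 54.9, 9.85 and 29.0 FPKM. Toll-like receptor genes, sensors of microbial products, fell in 9 of 11 cases and rose in 1 (median -0.65, adjusted p = 0.000704, 0.181 with an estimated correlation), with Tlr9 at 53.3, 21.8 and 33.9 FPKM, Tlr8 at 39.9, 16.3 and 27.4 and Tlr7 at 64.0, 36.3 and 51.3. With 15d-PGJ2-PC 8 of the 11 were higher than with 15d-PGJ2 (adjusted p = 0.000111, 0.15 with an estimated correlation).

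Genes of chemokines and their receptors fell in 15 of 26 cases with 15d-PGJ2 and rose in 2 (median -0.47, camera adjusted p = 0.00244, adjusted p = 0.124 with an estimated correlation). Cmklr1 fell by 1.47 on the log2 scale. The chaperonin that contains Tcp1, which folds actin and tubulin, rose in all 7 measured subunit genes (median 0.42, adjusted p = 5.85e-05, 0.181 with an estimated correlation), with Cct3 at 51.1, 113 and 89.6 FPKM. With 15d-PGJ2-PC 6 of the 7 were lower than with 15d-PGJ2 (median -0.23, adjusted p = 2.68e-05, 0.15 with an estimated correlation). The glutathione synthetase gene Gss was at 8.45, 50.9 and 24.8 FPKM.

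The tests of a graded response, of carry-over, of one common factor for RNAs without poly(A) tails and of one common factor on the log scale were chosen after the result was seen. A set of 61 genes, 22 of them keratin or keratin-associated and others of connective tissue, muscle or blood such as Col3a1, Eln, Actg2 and Hbb-bs, lay above 0.5 FPKM in each control and under 0.3 in each treated library. They summed to 115 ± 3.86 FPKM in controls, 1.61 ± 0.26 with 15d-PGJ2 and 1.3 ± 0.26 with 15d-PGJ2-PC. A graded response like that of other falling genes was tested on the score of the 7 tested stromal markers. Their loss on the log2 scale with 15d-PGJ2-PC was 1.131 times (SE 0.04) that with 15d-PGJ2. The median over 2786 other fallen genes was 0.512. This cannot decide for the 61 genes, of which only Col3a1 is in the stromal list. Of 13 listed stromal markers, 5 stayed at 1 FPKM or more in all treated libraries. The SE covers the spread between libraries, not between genes, and values near 0 with both compounds draw the ratio towards 1. RNA of another tissue in the control libraries is a candidate explanation. Among 36 further skin genes, of which Sfn and Jup lay at 1 FPKM or more in all treated libraries, 35 were higher in controls than in both treated groups, with sums of at least 18.3 against at most 11.5 FPKM (Sfn was the exception). All but Sfn, Sbsn, Jup and Ovol1 had control means under 1 FPKM, near the floor, and those named were also present in both treated groups. A loss of the transcripts of other tissues as a response of a few other cells in the cultures was not tested and stays open.

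A set of 8 RNAs without poly(A) tails, chosen after their values were seen, summed to 158 ± 20.5 FPKM in controls, 620 ± 17.8 with 15d-PGJ2 and 237 ± 16.2 with 15d-PGJ2-PC. Of 11 tested structural RNAs other than snoRNA, 8 rose with 15d-PGJ2 and 3 did not pass (median 1.42). They were taken by annotated class, except Rn45s, which was added by name and is also among the RNAs chosen by value. Rn7sk, the most abundant, was at 92.2, 422 and 160 FPKM. Carry-over that varies from library to library without regard to group was not settled. The sums of these 11 RNAs (604.7 to 634.7 FPKM with 15d-PGJ2, 137.6 to 175.8 in controls) differed by a step of 14.906 times the SD within groups on the log2 scale. Of 280 divisions of the 9 libraries into 3 groups, 1 reached it, the real one. That rank cannot count against carry-over, since the pattern was picked after the values were seen and Rn7sk makes up most of the summed FPKM. One common factor for all such RNAs and a change in the cells cannot be told apart. The median of 35 snoRNA genes lay at -1.147 (log2, SE 0.379 from resampling genes) relative to these 11. The snoRNA genes had an estimated median of 1.34 reads per library, under the limit of 20 set for excluding a common factor. Carry-over shared by the libraries of a group was not tested. Both tests replaced earlier forms, a within-group correlation of the 8 RNAs that had left carry-over open (0.123, percentile 92.4 of 10000 random sets) and a comparison of snoRNA genes with the 8 RNAs that had argued against a common factor, and the limit of 20 reads was set when the snoRNA values were known.

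The 15d-PGJ2-PC libraries lay between those of control and 15d-PGJ2 in the scores of the heat shock, Nrf2, proteasome and type I interferon lists. A mixture of control and 15d-PGJ2 RNA was argued against, since a mixture gives every list the same fraction of the 15d-PGJ2 change in FPKM. The median fractions were 0.337 (SE 0.044) for heat shock genes and 0.709 (SE 0.026) for the proteasome, a difference of 0.372 (SE 0.051). They were 0.548 for Nrf2 targets and 0.628 for type I interferon genes. These SEs come from resampling the genes of a list as if independent and do not measure the spread between libraries. One common factor on the log scale was argued against as well, with score ratios of the proteasome and the type I interferon list that differed by 0.288 (SE 0.046). Which list responds less depends on the scale, since the score ratio was 0.555 for heat shock genes and 0.455 for type I interferon genes. That the compound acts more weakly on some pathways than on others is a hypothesis, with dose, uptake and the pace of the response untested.

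The 6 libraries of a contrast can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. In each contrast 1 split, the real one, gave as many genes as reported: 5338 for 15d-PGJ2 against control (highest other split 2), 3147 for 15d-PGJ2-PC against control (highest other 1) and 2335 between the compounds (highest other 5). Every other split mixes both groups on each side, so the difference between the groups enters the residual variance. Low counts in those splits follow from this and do not measure the strength of the result.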
